A study of Mus musculus with 16 samples.

How the data were processed

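The series holds 16 RNA-seq libraries from cultured organs of Corti of newborn mice, 4 libraries for each combination of genotype (wild type, or heterozygous for a Rest allele without exon 4) and treatment (FK228 or solvent). Per the labels' protocols, organs of Corti from C57BL/6 mice of postnatal day 0 were cultured on Matrigel-coated inserts. They were exposed to 2 nM FK228 or 0.1% DMSO from day 1 to 1.5 and from day 3 to 3.5 in vitro, and RNA was pooled from 6 to 8 cultures per sample. Libraries were made by oligo dT priming, template switching and tagmentation and sequenced in paired ends, per the labels' protocols. The authors deposited a count of reads per gene for each library, made with STAR 2.5.2a on GRCm38.p4 per the submitters' processing notes, in 3 columns (unstranded and both strands). The authors also deposited a table of normalized signal for 21220 genes, made with DESeq2 per the submitters' processing notes.

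The unstranded counts were used, since the strand columns held equal shares of reads. Reads from antisense or overlapping genes are therefore not told apart. Each count file held 48709 gene rows, 92 ERCC spike-in rows and 22 rows of transgenes and synthetic spike-in RNA. The latter 2 kinds and the summary rows of unmapped, multimapping, ambiguous and unassigned reads were kept out of library sizes and tests. Reads in no gene made up 10.4% to 20.8% of reads, ERCC 0.156% to 0.393% of gene and spike-in counts, and transgenes at most 0.000106% of gene counts. Each normalized value times a factor per library (0.801 to 1.41) gave the deposited count, to within 0.001 reads, so the normalized values were used only as an alternative input. Names of all 17125 genes tested came from the authors' normalized table. Gene positions and types came from GENCODE M21, which held 99.3% of the gene identifiers. Depth ran from 12361027 to 23611571 gene counts per library, and 21653 to 22904 genes had at least 1 count.

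Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17125. A quasi-likelihood model with a mean for each of the 4 groups was fitted to all 16 libraries with TMM factors. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was called a change. Contrasts were heterozygous against wild type in solvent and with FK228, FK228 against solvent in each genotype, the difference of the FK228 effects (interaction), and heterozygous with FK228 against wild type in solvent. Errors of log2 fold changes are SEs of the model, and errors of CPM values are SDs of 4 libraries. Fold changes in parentheses are 2 raised to the log2 fold change. Library measures were compared by exact permutation.

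Gene lists written from general knowledge covered REST targets, REST corepressors, hair cells, stereocilia, supporting cells, spiral ganglion neurons, synapse and exocytosis, Schwann cells, macrophages, mesenchyme, cartilage, endothelium, stria vascularis and melanocytes, red blood cells, cell cycle, deacetylase inhibitor response, p53 response, immediate early genes and interferon response. Of 398 symbols in the 19 lists 395 were matched. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry, with adjustment over the 19 lists of a contrast. In 7 of 114 list tests the median, the mean and the test differed in sign (lowest adjusted p 0.756). Counts adjusted over the list alone used the p-values of its members.

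Genes named in the text were chosen by a rule. For each contrast these were Rest, then, among genes past the threshold with a name other than a clone number and with no overlap between the groups, the 10 with the smallest adjusted p that rose and the 10 that fell, and up to 4 members of each list with the smallest p. For the interaction the 5 and 5 with the smallest p were taken without the overlap condition. Genes with under 3 counts in every library of both groups were left out. CPM values were given for a subset of these genes. Lists, contrasts, this rule and the alternatives were fixed before the data were examined, except for the alternatives named as chosen later.

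Alternatives were DESeq2 1.42.0, RLE factors, no filter, a stricter filter, only the groups compared, the replicate number as a block, limma voom with quality weights, no mitochondrial genes, and each library left out in turn. Chosen after the data were seen were spike-in scaling, counts recovered from the normalized table, leaving out the 2 libraries with the lowest share of reads outside genes, and that share or the sex mix of the cultures as a covariate. Genes lowered by genotype and raised by FK228 were compared with 10000 lists matched on expression, 20 simulations without effects, and splits of the heterozygous solvent libraries. Sequence motifs were not analysed here.

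The tests were run first on simulated counts of 17125 genes, with 200 changed at random by 1.5-, 2- or 4-fold (67, 67 and 66 genes). For genotype in solvent edgeR recovered 41.8%, 70.1% and 93.9% of them with 2 false calls among 139, limma voom 41.8%, 67.2% and 92.4% with 2 among 136, and DESeq2 55.2%, 79.1% and 98.5% with 17 among 172. With edgeR the shares were 44.8%, 67.2% and 87.9% for FK228 in heterozygous cultures (4 false among 137), 46.3%, 79.1% and 93.9% in wild type (5 among 151), 40.3%, 71.6% and 90.9% for genotype with FK228 (5 among 140), and 43.3%, 73.1% and 87.9% for heterozygous with FK228 against wild type in solvent (9 among 145). For the interaction they were 25.4%, 53.7% and 77.3% with edgeR (8 among 112), 25.4%, 52.2% and 77.3% with limma voom (4 among 107) and 37.3%, 59.7% and 84.8% with DESeq2 (25 among 146). Far more than 200 genes changed with FK228 in the real data. The shares for contrasts of FK228 against solvent may therefore not carry over to them.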

Results

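The series measured polyadenylated RNA in organs of Corti, the sensory epithelium of the cochlea, taken from newborn C57BL/6 mice and kept in culture for 3.5 days. The mice were wild type or heterozygous for a Rest allele that lacks exon 4. REST is a zinc finger repressor of neuronal genes that recruits histone deacetylases. Cultures of both genotypes received 2 nM FK228, a cyclic peptide inhibitor of class I histone deacetylases also known as romidepsin, or the 0.1% DMSO solvent, during 2 exposures. Each of the 4 groups held 4 libraries, and each library came from RNA pooled over 6 to 8 cultures. The labels do not say whether the pools of a group came from separate litters, so p-values measure the spread between these pools.

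Gene counts ranged from 17462876 to 23611571 in the wild-type solvent libraries, 16224586 to 17656274 in wild type with FK228, 14627922 to 15674930 in the heterozygous solvent libraries and 12361027 to 14153838 in heterozygous with FK228. Libraries of the same group differed by more than sampling noise, so none was a copy of another. The first principal component of log CPM held 51.7% of the variance and separated the treatments, and the second held 10.4% and separated the genotypes. ERCC spike-in RNA took 0.178% ± 0.0175 (SD, n = 4) of gene and spike-in counts in wild type with solvent, 0.205% ± 0.0233 in wild type with FK228, 0.200% ± 0.0280 in heterozygous with solvent and 0.350% ± 0.0347 in heterozygous with FK228. The difference between the FK228 groups had an exact two-sided permutation p of 0.0286 (adjusted p = 0.0914 over 16 comparisons of library measures), the smallest p that 4 against 4 libraries can give. Scaling to the spike-ins in place of TMM factors moved the median log2 fold change of all 17125 genes tested by up to 0.89 below 0, to -0.72 for FK228 in heterozygous cultures, -0.16 for FK228 in wild type, -0.18 for genotype in solvent and -0.74 for genotype with FK228. Every change below is therefore relative to the bulk of transcripts in the same libraries.

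Rest (chromosome 5, 77265491 to 77286432 on GRCm38), the altered gene, passed the test in none of the 6 comparisons with TMM factors. In CPM, the wild-type solvent libraries 1 to 4 held 85.5, 78.6, 75.2 and 86.4, and the wild-type FK228 libraries 1, 2, 4 and 7 held 74.6, 79.9, 70.9 and 69.9. The heterozygous solvent libraries 1, 2, 4 and 5 held 78.1, 86.9, 94.8 and 93.4, and the heterozygous FK228 libraries 2 to 5 held 87.3, 81.1, 79.7 and 75.8. The log2 fold change between genotypes was 0.12 ± 0.08 (SE) in solvent (adjusted p = 0.654) and 0.13 ± 0.08 with FK228 (adjusted p = 0.525), or -0.06 (adjusted p = 0.844) and -0.60 (adjusted p = 0.000627) with spike-in scaling. FK228 gave -0.12 ± 0.08 in heterozygous cultures (adjusted p = 0.198; -0.83 and adjusted p = 1.71e-05 with spike-in scaling) and -0.14 ± 0.08 in wild type (adjusted p = 0.141). These are counts over the whole gene, so they do not test for the missing exon.

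**Figure D1:**
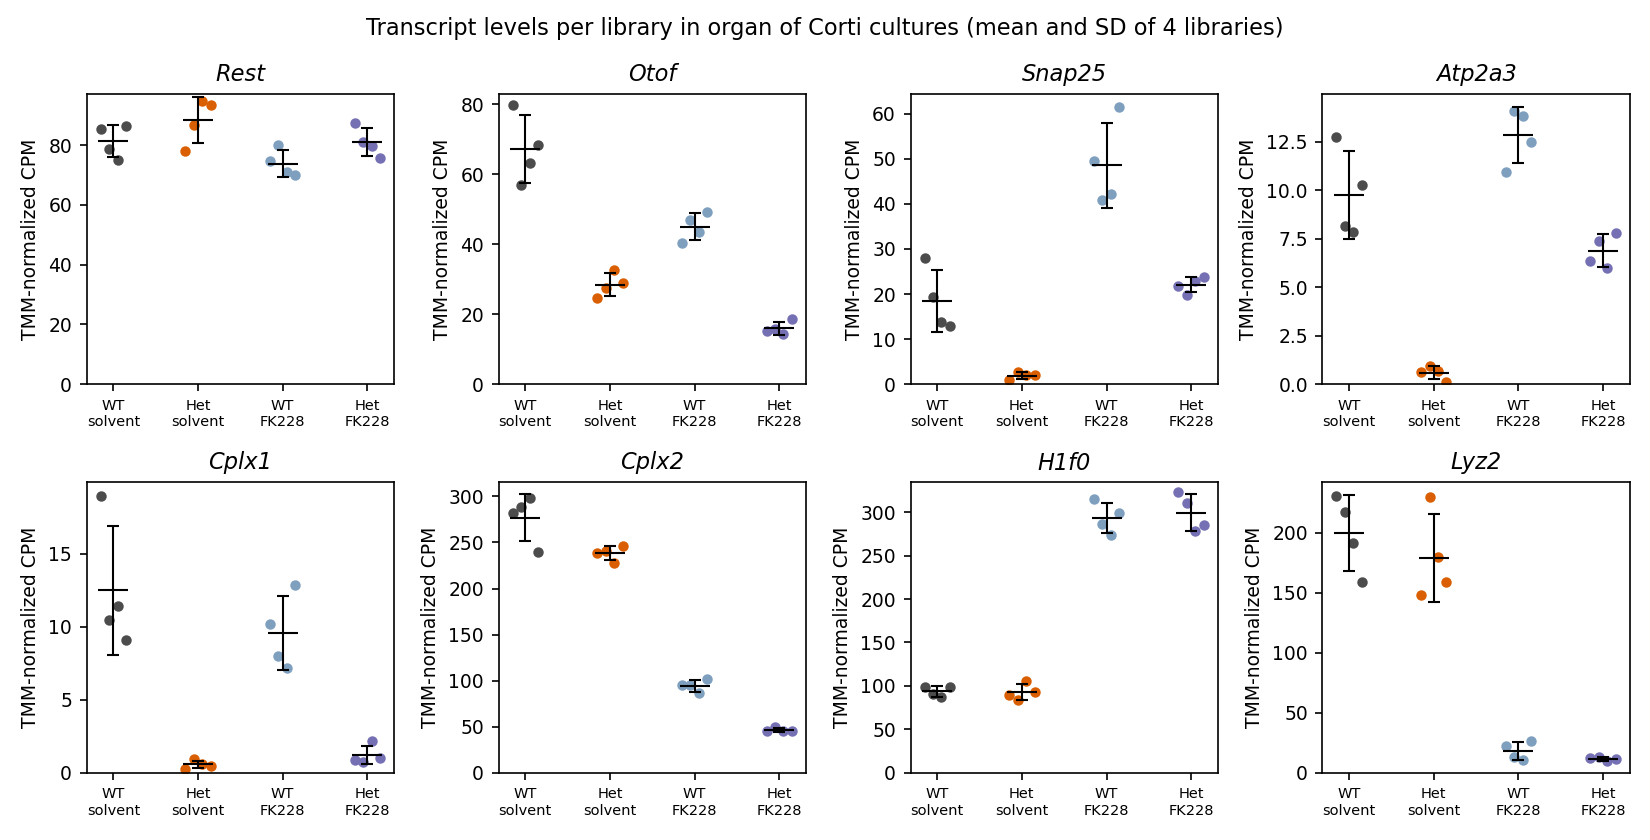
TMM-normalized CPM (linear axis from 0) of 8 genes in each of the 16 libraries, by group; points are libraries, horizontal marks are group means and bars are SDs of 4 libraries. Otof, Snap25, Atp2a3 and Cplx1 were lower in heterozygous (Het) than in wild-type (WT) cultures in solvent, while Rest held 81.4 CPM in wild type and 88.3 CPM in heterozygous cultures.

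The first comparison asked which transcripts differed between heterozygous and wild-type cultures without the drug. Several genes of vesicle release were lower in heterozygous cultures. Otof, which encodes otoferlin, the calcium sensor of hair cell synapses, fell from 67.2 ± 9.72 to 28.5 ± 3.34 CPM (mean ± SD, n = 4 per group), a log2 change of -1.24 ± 0.11 (SE, adjusted p = 2.12e-06). Snap25, a SNARE protein of vesicle fusion, fell 9.52-fold, from 18.5 ± 6.90 to 1.93 ± 0.76 CPM, and Cplx1, a complexin that clamps SNARE complexes, fell 21.5-fold, from 12.5 ± 4.44 to 0.57 ± 0.27 CPM. Atp2a3, a calcium pump of the endoplasmic reticulum, fell 16.3-fold, from 9.76 ± 2.27 to 0.59 ± 0.33 CPM.

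Chgb and Scg3, granins of dense-core vesicles, fell 7.34-fold and 6.43-fold. Gdap1, a mitochondrial outer membrane protein of neurons, fell 7.64-fold, and Golga7b, Nrsn1 and Lhfpl4 fell 20.2-fold, 15.4-fold and 4.03-fold. Adjusted p for these lowered genes ranged from 5.89e-08 for Atp2a3 to 2.96e-05 for Lhfpl4. In the other direction, Tmem163, which encodes a zinc transporter, rose from 0.69 ± 0.22 to 88.1 ± 5.54 CPM, and Mal2, Fam219b, Hipk1 and Vav3 rose 14.3-fold, 6.38-fold, 5.94-fold and 2.99-fold (highest adjusted p = 1.19e-05, for Vav3). Tsn and Arhgef11 rose 1.69-fold and 2.26-fold. Tmem163, Fam219b, Hipk1 and Arhgef11 each lie within 1 Mb of another gene that differed between genotypes in both treatments. Mal2, Vav3 and Tsn do not. A chromosome segment that differs between the mice may therefore explain the former, which was not tested for single genes. Rps3a3, a processed pseudogene on chromosome 13, was at 98.9 ± 4.68 CPM in heterozygous and 1.22 ± 0.14 CPM in wild-type libraries. Its count, and those of Rps3a2 (2.60-fold higher) and Tpm3-rs7 (12.0-fold higher), are uncertain, since reads can be shared with near-identical copies. The 3 Rps3a genes summed to 539 ± 47.4 CPM in wild-type and 477 ± 21.9 CPM in heterozygous solvent libraries, so the family was not higher in sum. The protein-coding Rps3a1 was lower, at -0.55 ± 0.07 (SE), and that call may be affected by shared reads too. It counts below among the genes lowered by genotype and raised by FK228.

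Over all 17125 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 206 genes higher and 141 lower in heterozygous cultures in solvent. The groups did not overlap for 1067 genes (6.23%), where chance gives 2.86%. Higher genes made up 59.4% of the calls, and 35.1% with spike-in scaling. DESeq2 called 550 genes, and a model that held the sex mix of the cultures as a term, chosen after the data were seen, called 228. Y-linked transcripts were at 199 ± 66.0 CPM (mean ± SD) in heterozygous and 92.7 ± 66.2 CPM in wild-type solvent libraries. The female transcript Xist was at 5.96 ± 6.56 and 17.1 ± 7.51 CPM, so sex was not balanced between these groups.

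Literature REST targets, neuronal genes with RE1 elements, moved together. Of 39 measured, 15 fell and none rose, 24 did not pass the test, and 25 fell when adjusted over the list alone. Their median log2 change was -0.79, with 33 of 39 below 0 (camera, adjusted p = 2.61e-24; adjusted p = 0.00436 with an estimated correlation). Of 19 spiral ganglion neuron markers 5 fell (3 without heterozygous solvent library 1 or wild-type solvent library 1), 9 when adjusted over the list alone, with a median of -0.68 (adjusted p = 2.82e-08; adjusted p = 0.0212 with an estimated correlation). They included Rbfox3, a neuronal splicing factor, at -1.63 ± 0.26 (adjusted p = 0.00139) and Nefh, the heavy neurofilament subunit, at -1.74 ± 0.28 (adjusted p = 0.00146). Of 27 synapse and exocytosis genes 4 fell, 9 when adjusted over the list alone. Among them were Snap25, Cplx1 and Syp, which encodes synaptophysin, at -1.43 ± 0.24 (adjusted p = 0.00261). The synapse list had a median of -0.22 (camera, adjusted p = 1.01e-06; adjusted p = 0.00753 with an estimated correlation). With spike-in scaling 17 REST targets, 8 neuron markers and 7 synapse genes fell, and 2 neuron markers fell without the 2 libraries with the lowest share of reads outside genes (3 with limma voom). The REST list shares 3 genes with the neuron list and 5 with the synapse list.

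Of 46 hair cell genes 4 fell and 42 did not pass the test, 7 lower when adjusted over the list alone, with a median of -0.29. Otof was joined by Cabp2, a calcium-binding protein of hair cell synapses, at -2.62 ± 0.40 (adjusted p = 0.00103), and by Pvalb, the calcium buffer parvalbumin, at -1.10 ± 0.22 (adjusted p = 0.00994). The list passed camera (adjusted p = 1.78e-06) but not with its own estimate (adjusted p = 0.206 with an estimated correlation). Stereocilia and mechanotransduction genes, 23 of which are also in the hair cell list, had 1 of 26 lower (Lhfpl5), 1 when adjusted over the list alone, and a median of -0.23 (adjusted p = 0.0054; adjusted p = 0.29 with an estimated correlation). Lhfpl5 kept its call only without heterozygous solvent library 4 or heterozygous FK228 library 2 or 5, and lost it in the 13 other fits that left out a library (adjusted p up to 0.148). Macrophage markers had a median of -0.30 with none of 14 past the test, also when adjusted over the list alone (camera, adjusted p = 0.0148; adjusted p = 0.439 with an estimated correlation). Supporting cell markers had 1 of 29 higher (Epyc, not past the test without heterozygous solvent library 4 or 5 or wild-type solvent library 2 or 3; adjusted p up to 0.101), 1 when adjusted over the list alone, and a median of -0.09 (camera, adjusted p = 0.878). No Schwann cell, mesenchyme or cell cycle gene passed in either direction, also when adjusted over each list alone (camera, adjusted p = 0.932, 0.821 and 0.0924).

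**Figure D2:**
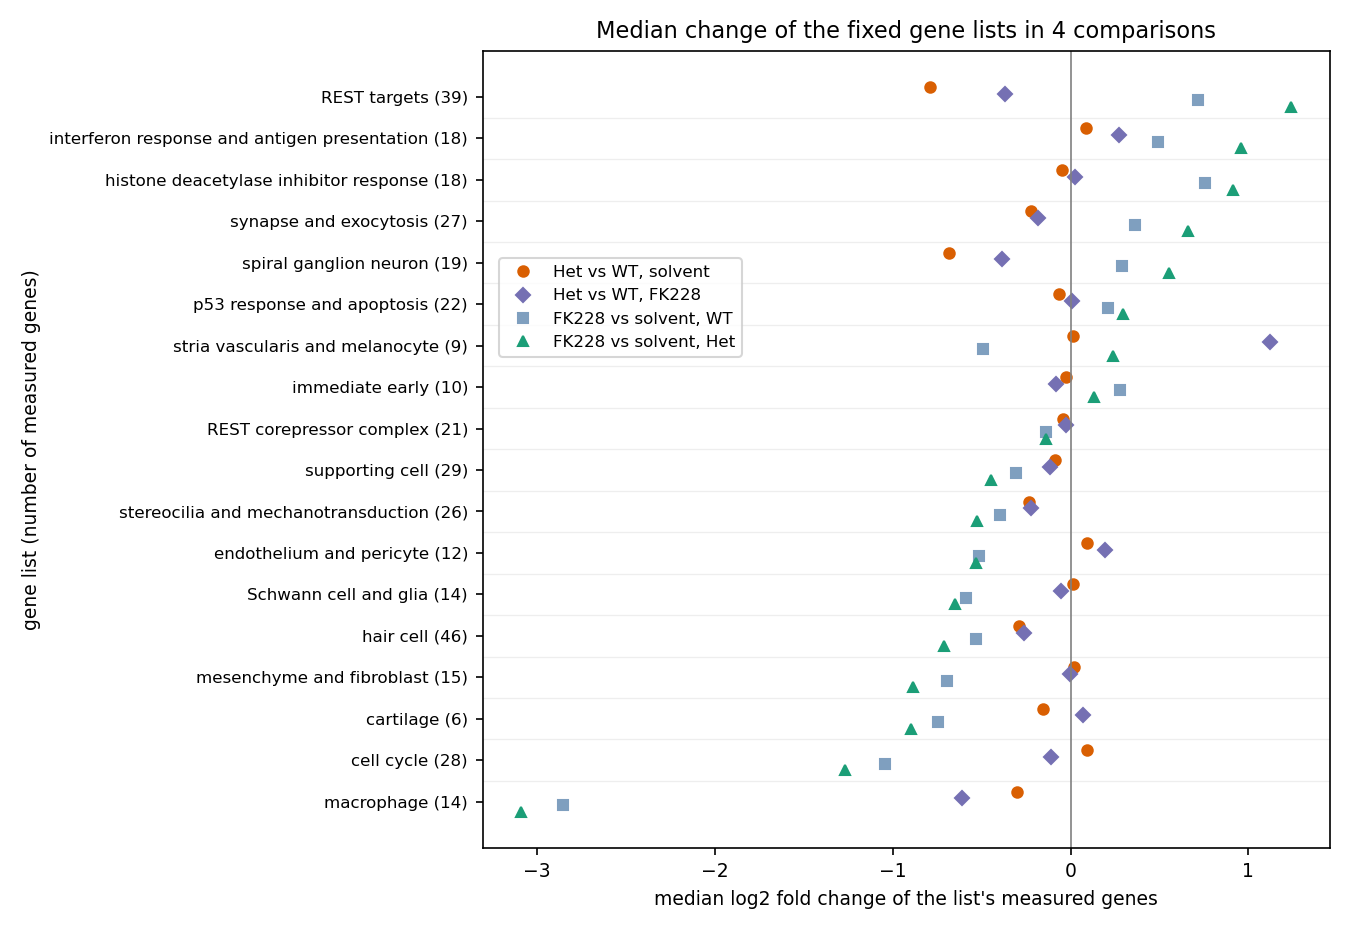
Median log2 fold change (horizontal axis) of the measured genes of 18 fixed gene lists (vertical axis, number of measured genes in parentheses), in 4 comparisons given by marker shape and colour; Het is heterozygous and WT is wild type. Macrophage markers had medians of -3.09 and -2.86 with FK228, and REST targets lay at -0.79 between genotypes in solvent and at 1.24 with FK228 in heterozygous cultures.

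The next comparison asked what FK228 did to wild-type cultures. Pou4f1, a transcription factor of sensory neurons, rose from 9.37 ± 0.82 to 94.6 ± 17.7 CPM (n = 4 per group), a log2 change of 3.33 ± 0.14 (SE, adjusted p = 2.17e-11). H1f0, the linker histone of differentiated cells and a classical gene of deacetylase inhibition, rose from 93.6 ± 5.86 to 293 ± 17.5 CPM. Macrophage transcripts fell strongly: Lyz2, which encodes lysozyme, fell from 200 ± 31.7 to 18.0 ± 7.74 CPM, and C1qa, of complement, fell from 34.0 ± 1.33 to 4.39 ± 0.70 CPM.

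Among the other genes with the smallest adjusted p, Cldn10, a tight junction claudin, rose 18.0-fold, and Eaf2, a transcription elongation factor, rose 15.98-fold. Nrip3 rose 13.7-fold, Reep6 rose 5.05-fold, Nmnat2, an NAD-synthesizing enzyme of axons, rose 4.83-fold, and Tango2 rose 3.67-fold. Sephs1 fell 4.15-fold, Kdelc2 fell 5.57-fold, Plpp5 fell 4.05-fold, and Cplx2, a complexin, fell 2.93-fold, from 277 ± 25.7 to 94.7 ± 6.50 CPM. Gpx7, Ubxn8, Peg12 and Csad fell 3.33-fold, 3.26-fold, 3.14-fold and 2.97-fold. Hmgn2, a nucleosome-binding protein, fell 2.94-fold. The adjusted p of these genes was 5.72e-10 or smaller.

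FK228 changed 8394 of 17125 genes in wild type, 4061 upward and 4333 downward. Of these, 2703 changed at least 2-fold. The groups did not overlap for 7649 genes (44.7%), where chance gives 2.86%. Higher genes made up 48.4% of the calls, and 30.8% with spike-in scaling.

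By cell type, all 14 macrophage markers fell in wild type, with a median of -2.86 (camera, adjusted p = 9.71e-10; adjusted p = 0.0494 with an estimated correlation). Of 18 genes known to rise with deacetylase inhibitors 11 rose and 2 fell (adjusted p = 0.000112; adjusted p = 0.0494 with an estimated correlation), among them Txnip (3.70-fold), Hist1h1c (6.33-fold) and Mt1 (2.93-fold). These were the lists that held with an estimated correlation. Mesenchyme genes fell for 12 and rose for 1 of 15, such as Prrx1 (5.64-fold lower) and the collagen gene Col3a1 (2.88-fold lower; list adjusted p = 0.000443; adjusted p = 0.243 with an estimated correlation). Cell cycle genes fell for 22 of 28 and rose for 2, with Myc 3.16-fold and the cyclin gene Ccnd1 2.86-fold lower (adjusted p = 8.55e-05; adjusted p = 0.496 with an estimated correlation). Schwann cell markers fell for 9 of 14 and rose for 2 (adjusted p = 0.0281; adjusted p = 0.347 with an estimated correlation), and supporting cell markers fell for 14 of 29 and rose for 2 (adjusted p = 0.0182; adjusted p = 0.496 with an estimated correlation). Supporting cell examples were Gjb6, a gap junction gene, at -1.68 ± 0.20 and Sox2 at -0.86 ± 0.14. Adjusted over each list alone, the counts in this paragraph were the same.

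Many, but not all, hair cell and stereocilia genes also fell in wild type with FK228. Of 46 hair cell genes 24 fell and 1 rose, 25 and 1 when adjusted over the list alone, with a median of -0.53 (camera, adjusted p = 0.00243; adjusted p = 0.435 with an estimated correlation). Chrna9 and Chrna10, the subunits of the efferent acetylcholine receptor of hair cells, fell 5.82-fold and 3.51-fold (adjusted p = 2.84e-05 and 1e-05). Stereocilia genes fell for 13 of 26 and rose for 1, 14 and 1 when adjusted over the list alone, including Ptprq (2.58-fold; list adjusted p = 0.0182; adjusted p = 0.428 with an estimated correlation). REST targets went the other way: 21 of 39 rose and 2 fell, the same numbers when adjusted over the list alone, with a median of 0.71 (adjusted p = 0.00181; adjusted p = 0.347 with an estimated correlation). Mapk8ip2, a scaffold of neuronal kinases, rose 3.34-fold, Chga, chromogranin A, rose 3.89-fold, and Syt7, a synaptotagmin, rose 2.79-fold. Synapse genes rose for 12 of 27 and fell for 2, also when adjusted over the list alone, with Syngr3, a vesicle protein, at 5.91-fold and Stx1a, a syntaxin, at 2.54-fold (adjusted p = 0.0182; adjusted p = 0.243 with an estimated correlation). Spiral ganglion markers rose for 7 and fell for 7 of 19, also when adjusted over the list alone, with a median of 0.29 (adjusted p = 0.434). Interferon and antigen presentation genes rose for 10 of 18 and fell for 2, also when adjusted over the list alone, with Isg15 at 3.04-fold and Bst2 at 2.31-fold (adjusted p = 0.0182; adjusted p = 0.496 with an estimated correlation).

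The same question was asked of heterozygous cultures. Snap25 rose from 1.93 ± 0.76 to 22.1 ± 1.72 CPM with FK228 (n = 4 per group), a log2 change of 3.50 ± 0.28 (SE, adjusted p = 1.28e-08). Pou4f1 rose from 9.95 ± 1.39 to 83.7 ± 10.3 CPM, H1f0 from 93.0 ± 9.61 to 299 ± 20.96 CPM, and Syngr3 from 7.57 ± 0.67 to 71.9 ± 2.29 CPM. Cplx2 fell from 238 ± 7.45 to 46.7 ± 2.36 CPM, Lyz2 from 179 ± 36.4 to 11.6 ± 1.51 CPM, and Ltbp1, which binds latent TGF-beta, from 507 ± 39.2 to 111 ± 12.2 CPM. Otof fell further, from 28.5 ± 3.34 to 16.04 ± 1.83 CPM, at -0.83 ± 0.12 (adjusted p = 1.42e-05).

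Nrip3, Eaf2 and Celf5, an RNA-binding protein of neurons, rose 19.3-fold, 18.9-fold and 10.9-fold in heterozygous cultures. Reep6, Nmnat2, Tango2 and Mdm1 rose 7.82-fold, 5.53-fold, 3.70-fold and 3.23-fold. Sephs1, Peg12, Csad and Hmgn2 fell 4.48-fold, 3.74-fold, 3.41-fold and 3.13-fold. Anp32b, a histone chaperone, fell 2.98-fold and the transcription factor Nfia fell 2.76-fold. The adjusted p of these genes was 2.65e-10 or smaller. In all, 4068 genes rose and 4229 fell, and 2766 of these 8297 changed at least 2-fold. The groups did not overlap for 7302 genes (42.6%), where chance gives 2.86%. Higher genes made up 49.0% of the calls, and 7.003% with spike-in scaling.

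All 14 macrophage markers fell in heterozygous cultures, also when adjusted over the list alone, with a median of -3.09 (camera, adjusted p = 1.63e-10; adjusted p = 0.0443 with an estimated correlation). Of 18 deacetylase inhibitor genes 14 rose and 2 fell, also when adjusted over the list alone (adjusted p = 6.02e-05; adjusted p = 0.0443 with an estimated correlation). REST targets rose for 25 and fell for 2 of 39, 26 and 2 when adjusted over the list alone, with a median of 1.24 (adjusted p = 6.52e-06; adjusted p = 0.154 with an estimated correlation). Examples were Ina, a neuronal intermediate filament gene (10.9-fold), Mapk8ip2 (8.79-fold) and Rundc3a (4.73-fold). Synapse genes rose for 14 and fell for 3 of 27, also when adjusted over the list alone, with a median of 0.66 that lay at -0.05 with spike-in scaling (adjusted p = 0.00174; adjusted p = 0.0793 with an estimated correlation). Spiral ganglion markers rose for 9 and fell for 4 of 19, 9 and 5 when adjusted over the list alone, with a median of 0.56 that lay at -0.13 with spike-in scaling (adjusted p = 0.178). Interferon genes rose for 10 and fell for 2 of 18, also when adjusted over the list alone, including Rsad2 (9.87-fold), Psmb9 (3.19-fold) and Isg15, from 2.76 ± 0.68 to 10.8 ± 3.60 CPM (adjusted p = 0.00228; adjusted p = 0.381 with an estimated correlation). With spike-in scaling fewer rose: 6 deacetylase inhibitor genes, 14 REST targets, 6 synapse genes, 6 spiral ganglion markers and 7 interferon genes.

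Hair cell genes fell for 19 and rose for 2 of 46 in heterozygous cultures, also when adjusted over the list alone, with a median of -0.71 (camera, adjusted p = 0.00243; adjusted p = 0.381 with an estimated correlation). Ocm, the outer hair cell calcium buffer oncomodulin, fell from 21.02 ± 1.57 to 8.81 ± 0.94 CPM, and Clrn1 and Ptprq, proteins of the hair bundle, fell 2.63-fold and 2.38-fold. Stereocilia genes fell for 12 and rose for 2 of 26, also when adjusted over the list alone (adjusted p = 0.0324; adjusted p = 0.381 with an estimated correlation). Cell cycle genes fell for 25 and rose for 1 of 28, 26 and 1 when adjusted over the list alone, such as Ccna2 (3.80-fold) and Mki67 (3.68-fold; list adjusted p = 3.63e-07; adjusted p = 0.381 with an estimated correlation). Mesenchyme genes fell for 12 and rose for 1 of 15 (adjusted p = 0.000135; adjusted p = 0.155 with an estimated correlation), and supporting cell markers fell for 16 of 29 (adjusted p = 0.00243; adjusted p = 0.381 with an estimated correlation), both counts also when adjusted over each list alone. Schwann cell markers fell for 9 and rose for 2 of 14, 10 and 2 when adjusted over the list alone (adjusted p = 0.0101; adjusted p = 0.21 with an estimated correlation). With spike-in scaling more fell: 40 hair cell genes, 21 stereocilia genes, 14 mesenchyme genes, 27 supporting cell markers and 12 Schwann cell markers.

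Set against each other, the FK228 effects in both genotypes were close. They shared 3274 raised genes, where independent lists of these sizes would share 965, and 3469 lowered genes, where 1070 would be shared, and 3 genes went up in heterozygous and down in wild type and 3 the reverse. The comparisons have no library in common. Across 17125 genes the log2 fold changes had a Pearson correlation of 0.876 and a Spearman correlation of 0.870; genes are not independent replicates.

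**Figure D3:**
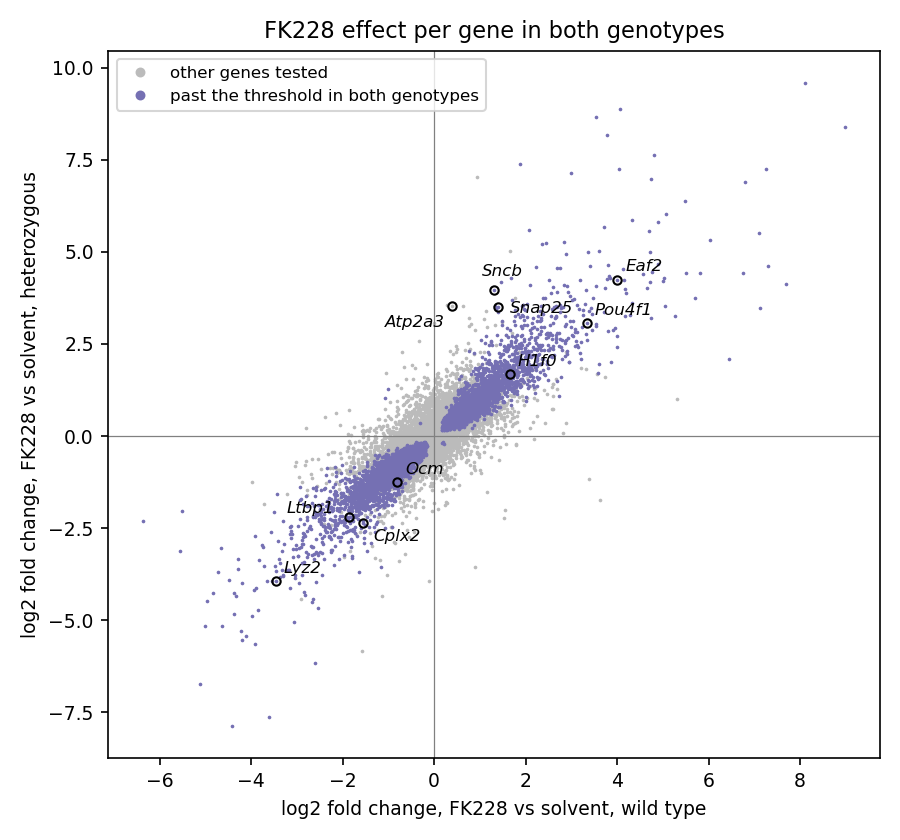
Log2 fold change of FK228 against solvent in wild-type (horizontal axis) and heterozygous cultures (vertical axis) for 17125 genes, with genes past adjusted p of 0.05 in both genotypes in purple and 10 named genes circled. Most genes follow the diagonal (Pearson correlation 0.876), while Atp2a3, Sncb and Snap25 lie above it and Cplx2 lies below it.

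The interaction test asked for which genes the FK228 effect differed between genotypes. Atp2a3 rose by 3.13 ± 0.37 (SE, log2) more in heterozygous than in wild-type cultures (adjusted p = 0.0014), from 0.59 ± 0.33 to 6.88 ± 0.84 CPM in the former and from 9.76 ± 2.27 to 12.8 ± 1.44 CPM in the latter (n = 4 per group). Sncb, beta-synuclein, rose by 2.65 ± 0.41 more (adjusted p = 0.0244), from 0.27 ± 0.10 to 4.32 ± 1.27 CPM against 1.79 ± 0.29 to 4.46 ± 0.73 CPM. Snap25 rose by 2.12 ± 0.35 more (adjusted p = 0.0429), and Cplx2 had a difference of -0.80 ± 0.10 (adjusted p = 0.00328). These 4 were the genes called among 17125, while 995 had an unadjusted p under 0.05. Higher genes made up 75% of the calls, and 0.221% of the 4069 genes called with spike-in scaling. Next in rank, Arhgap44 had -0.61 ± 0.10 (adjusted p = 0.0508) and Ina 2.09 ± 0.40 (adjusted p = 0.144). DESeq2 called 29 genes and limma voom called 2. Leaving out heterozygous solvent library 1 or 4, heterozygous FK228 library 2, wild-type solvent library 1, or wild-type FK228 library 1, 2 or 4 left 2 genes. Of 16 fits that left out a library, Snap25 lost its call in 12 (adjusted p up to 0.124) and kept it without heterozygous solvent library 2, wild-type solvent library 3 or 4, or wild-type FK228 library 7, and Sncb lost its call in 8 (adjusted p up to 0.0786).

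REST targets had a median difference of 0.34 between the FK228 effects, heterozygous minus wild type, that lay at -0.20 with spike-in scaling (camera, adjusted p = 5.23e-06; adjusted p = 0.399 with an estimated correlation). Of 39, 1 (Snap25) passed over all genes and 4 when adjusted over the list alone. Stria vascularis and melanocyte genes had a median of 0.86 over 9 genes (adjusted p = 0.000119; adjusted p = 0.399 with an estimated correlation). Interferon genes had 0.21, or -0.36 with spike-in scaling (adjusted p = 0.0146; adjusted p = 0.75 with an estimated correlation). Cell cycle genes had -0.22 (adjusted p = 0.0045; adjusted p = 0.813 with an estimated correlation) and macrophage markers -0.27 (adjusted p = 0.0318; adjusted p = 0.721 with an estimated correlation). None of the 19 lists passed fry, a test of whether a list's genes move on balance in the same direction.

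With FK228 in both genotypes, heterozygous cultures still held less Otof, at 16.04 ± 1.83 CPM against 45.1 ± 3.84 CPM in wild type (n = 4 per group), a log2 change of -1.49 ± 0.12 (SE, adjusted p = 2.44e-07). Cplx1 was 7.77-fold lower, at 1.21 ± 0.64 against 9.54 ± 2.54 CPM, and Snap25 was 2.20-fold lower, at 22.1 ± 1.72 against 48.5 ± 9.38 CPM (adjusted p = 0.00837). Cplx2 was lower too, at 46.7 ± 2.36 against 94.7 ± 6.50 CPM. Nefl, the light neurofilament subunit, was at 67.2 ± 22.8 CPM against 186 ± 56.8 CPM (adjusted p = 0.00389).

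Gdap1, Chgb, Nrsn1 and Golga7b were 5.46-fold, 4.02-fold, 9.75-fold and 9.40-fold lower in heterozygous cultures with FK228, and Mgat5 and Zbtb21 were 1.92-fold and 1.79-fold lower. Tmem163 (66.4-fold), Mal2 (11.4-fold), Hipk1 (6.12-fold), Fam219b (4.62-fold) and Pigt (2.499-fold) were higher. The test called 207 genes higher and 159 lower, with 105 of the higher and 55 of the lower also called in solvent, where independent lists would share 2.49 and 1.31 genes. The groups did not overlap for 1513 genes (8.84%), where chance gives 2.86%. Higher genes made up 56.6% of the calls, and 0.747% with spike-in scaling, under which 12857 genes passed. DESeq2 called 638 genes, and leaving out wild-type FK228 library 7, 4 or 1 left 188, 221 or 237 genes, and leaving out heterozygous FK228 library 4 left 235.

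REST targets were lower for 9 of 39 with FK228, 13 when adjusted over the list alone, with a median of -0.37 (camera, adjusted p = 1.5e-09; adjusted p = 0.105 with an estimated correlation). Hair cell genes were lower for 4 of 46, 5 when adjusted over the list alone: Otof, Cabp2 (5.78-fold), the calcium-binding protein gene Calb2 (1.85-fold) and Pvalb (2.14-fold; list adjusted p = 1.17e-05; adjusted p = 0.226 with an estimated correlation). Synapse genes were lower for 4 of 27, 5 when adjusted over the list alone (adjusted p = 0.00149; adjusted p = 0.105 with an estimated correlation), and spiral ganglion markers for 2 of 19, 4 when adjusted over the list alone (adjusted p = 0.000108; adjusted p = 0.118 with an estimated correlation). With spike-in scaling 33 REST targets, 36 hair cell genes and 22 synapse genes were lower. Macrophage markers were lower for 1 of 14 (C1qc), 3 when adjusted over the list alone, with a median of -0.61 (adjusted p = 1.26e-06; adjusted p = 0.105 with an estimated correlation). C1qc lost its call without heterozygous FK228 library 2 or 5 or wild-type FK228 library 1, 2 or 7 (adjusted p 0.0505 to 0.0941) and with limma voom (adjusted p = 0.115). Stria vascularis and melanocyte genes had a median of 1.12, with 0 of 9 past the test over all genes and 7 higher when adjusted over the list alone (adjusted p = 2.6e-06; adjusted p = 0.129 with an estimated correlation).

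The last contrast set heterozygous cultures with FK228 against untreated wild type, to see how far apart they stayed. Otof stood at 16.04 ± 1.83 against 67.2 ± 9.72 CPM (n = 4 per group), a log2 change of -2.07 ± 0.12 (SE, adjusted p = 3.49e-10). Cabp2, Grxcr2 and Ocm were 10.96-fold, 4.42-fold and 2.20-fold lower. Cplx1 and Gdap1 were 10.2-fold and 5.20-fold lower, whereas Mapk8ip2 was 3.15-fold higher. Of 46 hair cell genes 30 were lower and 2 higher, 31 and 2 when adjusted over the list alone, with a median of -0.96 (camera, adjusted p = 9.04e-06; adjusted p = 0.264 with an estimated correlation). Of 39 REST targets 15 were higher and 8 lower, also when adjusted over the list alone (adjusted p = 0.521). With spike-in scaling 3 REST targets were higher and 19 lower, and 44 hair cell genes were lower. In all, 4258 genes were higher and 4432 lower, and higher genes made up 49.0% of the calls, or 5.03% with spike-in scaling. The groups did not overlap for 7821 genes (45.7%), where chance gives 2.86%.

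A final question was whether FK228 moved the transcripts lowered by genotype back up. Of the 141 genes lower in heterozygous than in wild-type cultures in solvent, FK228 raised 77 (54.6%) in heterozygous cultures and lowered 21. Atp2a3 rose from 0.59 to 6.88 CPM and Snap25 from 1.93 to 22.1 CPM, whereas Otof fell. Of the 15 lowered REST targets 13 rose. With FK228 5 of these 15 stayed below untreated wild type, 5 did not differ past the test and 5 lay above it. The 4 lowered hair cell genes all stayed below untreated wild type, with a median FK228 change of -0.68. Otof (-0.83) and Lhfpl5 (-0.53) fell with FK228, whereas Cabp2 (-0.83) and Pvalb (0.09) did not pass the test. Over the 141 genes, 73 stayed lower than in untreated wild type, 37 did not differ past the test and 31 were higher. Against wild type with FK228, 55 of the 141 genes were lower and 0 higher. Of the 15 REST targets 8 were lower and 0 higher in that comparison. Genes above untreated wild type were therefore not above wild type with the same drug.

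Independent lists of these sizes would share 33.5 raised genes, and 10000 random lists matched on expression had a median of 33 and at most 54. In wild type FK228 raised 51 of the 141 genes (above 99.98% of the random lists) and lowered 36. That contrast uses the wild-type solvent libraries of the genotype comparison with the same sign, which pushes lowered genes further down by chance, and no simulation was made for it. Of the 206 genes raised by genotype, FK228 lowered 58 in heterozygous cultures and raised 25, where random lists had a median of 52 lowered, and in wild type it lowered 24 and raised 42. The genotype comparison and FK228 in heterozygous cultures use the heterozygous solvent libraries with opposite sign, so chance alone also moves genes back. In 20 simulations with no effect, 93.7% (90.1% to 96.5%) of the 141 lowest genes lay above 0 for FK228, against 93 genes (66.0%) observed. The simulated genes were low by noise alone, with at most 1 gene called for genotype, whereas the 141 observed genes all passed the test. The simulated share is therefore no direct measure of chance for the observed genes. The covariance of the log2 changes was -0.09, and -0.04 in the simulations. The heterozygous solvent libraries were also split in pairs, so that none served both contrasts. With libraries 1 and 2 for genotype, FK228 raised 90 of 288 genes lowered by genotype (31.3%). The other splits gave 48.3% to 54.1%, 27 to 43 genes. In the main fit FK228 raised 23.8% of all genes tested in heterozygous cultures. DESeq2 gave 124 genes, a fit of only the groups compared gave 34, limma voom gave 37, and leaving out heterozygous solvent library 1 gave 45. With spike-in scaling 58 of 192 lowered genes rose (30.2%), and 45.8% of them lay above 0, against 66.0% with TMM factors.

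**Figure D4:**
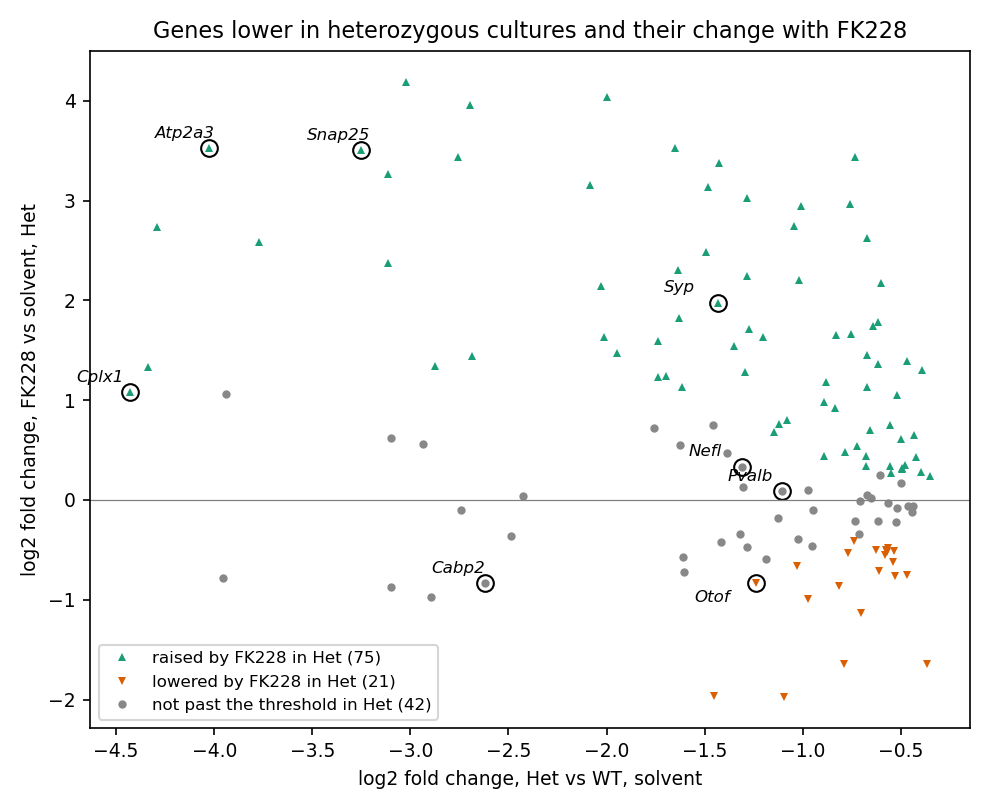
Log2 fold change of genotype in solvent (horizontal axis) and of FK228 in heterozygous cultures (vertical axis) for genes lower in heterozygous (Het) than in wild-type (WT) cultures; of 141 genes, 3 with under 3 counts over the heterozygous solvent libraries are not drawn. Of the 141, 77 rose, 21 fell and 43 did not pass the test, with Snap25 and Atp2a3 among those that rose and Otof among those that fell.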

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

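The tests of the transgene reads and the spike-in scaling were chosen only after those reads were seen.

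The log2 change with FK228 differed between the genotypes for 4 genes by the interaction test (edgeR, n = 4 per group). On the log2 scale Atp2a3 (difference 3.13, adjusted p = 0.0014), Sncb (2.65, adjusted p = 0.0244) and Snap25 (2.12, adjusted p = 0.0429) rose more in heterozygous cultures, and Cplx2 fell more (-0.80, adjusted p = 0.00328). The rises started from low levels, with 2 to 14 counts of Atp2a3, 2 to 6 of Sncb and 13 to 42 of Snap25 per heterozygous solvent library. When a library was left out, Snap25 lost its call in 12 of 16 fits and Sncb in 8. By list, REST targets (0.34) and stria vascularis and melanocyte genes (0.86) had higher differences, as did interferon genes (0.21), and cell cycle genes (-0.22) and macrophage markers (-0.27) had lower ones. With spike-in scaling the differences of the REST targets and the interferon genes lay below 0, at -0.20 and -0.36. These 5 lists passed camera with adjusted p from 5.23e-06 to 0.0318, and none passed with an estimated correlation (lowest adjusted p = 0.399).

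Some libraries stood apart from the other 3 of their group. Nefl was at 101 CPM in heterozygous FK228 library 4 (54.2 to 59.1 in the others), Cplx2 at 50.2 CPM in heterozygous FK228 library 3 (45.2 to 45.6), and Syngr3 at 17.5 CPM in wild-type solvent library 1 (8.47 to 9.19) and at 72.6 CPM in wild-type FK228 library 1 (61.8 to 63.5). Wild-type solvent library 1 also held 23.61 M gene counts (17.46 to 18.5 M in the others) and 10.8% of reads outside genes (16.2% to 16.3%). Heterozygous FK228 library 5 held 19.7% of reads outside genes (17.5% to 17.8%), and 6.46% of the reads of heterozygous FK228 library 2 mapped to several places (6.10% to 6.12%). Of 100 groups examined 8 had a library apart, where chance gives about 1 in 20, or 5. A search for single libraries does not show a group that divides into pairs. Heterozygous solvent libraries 1 and 2 held 19.7% and 17.9% of reads outside genes, and libraries 4 and 5 held 10.4% and 12.9%. On the third principal component, with 7% of the variance, libraries 1 and 2 lay at -27.5 and -26.5, and libraries 4 and 5 at 45.2 and 18.0. The ERCC share of 0.350% in heterozygous cultures with FK228, above the other groups, may come from less RNA per sample or from uneven addition of the spike-in, and with spike-in scaling 12857 genes passed for genotype with FK228. No test told these apart.

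A row for a CRE-ERT2 transgene, outside the gene counts, held 72 reads over the 8 heterozygous libraries, 5 to 16 in each, and 0 in each of the 8 wild-type libraries (exact permutation p = 0.000155, the smallest it can be). Reads of the mouse gene Esr1 counted on that row would have given 113 reads in wild type, and carry-over in proportion to library size 91.7 reads, so both are argued against. A CRE-ERT2 transgene carried by the mice of the heterozygous group, with reads in 8 of 8 libraries, may explain them and stays open. It would be present in exactly the libraries of the heterozygous group, so any effect of it on other genes cannot be separated from that of the Rest allele.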

How the results depend on the processing

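Tests with spike-in scaling, the covariates, the recovered counts and without 2 libraries were chosen only after the results were seen. Where a value below changed, the cause was not tested. Named genes kept their direction and side of the threshold in 7679 of 7840 values over 30 settings, 136 lost their call, 23 gained it, and 2 reversed. The 2 reversed values were those of Rest between genotypes with spike-in scaling, at -0.056 in solvent and -0.598 with FK228. Many genes were named for their small adjusted p in these same data, so keeping their calls was partly fixed by that choice. Of all genes called, as few as 64.8% for genotype in solvent and 50.3% for genotype with FK228 were kept when a library was left out. Genotype in solvent (347 genes) gave 550 with DESeq2, 228 with the sex mix as a covariate, and 237 (without wild-type solvent library 4) to 384 (without heterozygous FK228 library 4) when a library was left out. Genotype with FK228 (366) gave 638 with DESeq2, 12857 with spike-in scaling, 592 with the share of reads outside genes as a covariate, 188, 221 and 237 without wild-type FK228 library 7, 4 and 1, 235 without heterozygous FK228 library 4, and up to 421 (without heterozygous solvent library 4). The FK228 counts stayed within 1.5 times of 8297 and 8394 in all settings, with 7588 to 8466 and 7532 to 8604 when a library was left out. The same held for heterozygous with FK228 against wild type in solvent (8690; 7957 to 8932). The interaction (4) gave 29 with DESeq2, 2 with limma voom, 10 with no low-count filter, 4069 with spike-in scaling, 8 with the share of reads outside genes as a covariate, 2 without the 2 libraries with the lowest such share, and 2 (among others without heterozygous solvent library 1) to 6 (without heterozygous FK228 library 4). The counts recovered from the normalized table gave the same numbers of genes.

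Lowered genes that FK228 raised (77) became 124 with DESeq2, 34 with only the groups compared, 37 with limma voom, 122 with the share of reads outside genes and 49 with the sex mix as a covariate, and 45 (without heterozygous solvent library 1) to 82 (without heterozygous solvent library 5). With separate heterozygous solvent libraries for each contrast they were 40, 28, 34, 27, 43 and 90. Spike-in scaling gave 58 of 192 (30.2%, against 54.6%). With an estimated correlation in place of the preset, the lists past the threshold went from 7 to 3 for genotype in solvent, from 11 to 2 and from 12 to 2 for FK228 in heterozygous and wild-type cultures, from 9 to 0 for genotype with FK228, from 5 to 0 for the interaction (0 with fry), and from 9 to 0 for heterozygous with FK228 against wild type in solvent. Among the 7 was the red blood cell list, with 1 measured gene. Replicate numbers did not pair the samples: same-numbered libraries correlated at -0.231 to 0.169, and not every library correlated best with its own number. As a replicate block shared by all groups, they gave 211 genes for genotype in solvent, 107 for genotype with FK228, and 0 for the interaction (edgeR; 995 at an unadjusted p under 0.05 without the block), 0 also within genotype. With that block 3 REST targets, 1 hair cell gene and 2 synapse genes were lower between genotypes with FK228 (9, 4 and 4 without it). REST binding motifs were not run, as no genome sequence was used here. In simulations with 4 libraries per group edgeR found 41.8% of 1.5-fold changes for genotype in solvent and 25.4% for the interaction, so many changes of that size are missed in this design.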

Other observations

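The tests of spike-in scaling, of genes changed in both treatments, of lower REST targets and of other splits in this part were chosen only after the results were seen.

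REST corepressor genes, which encode the partners through which REST silences genes, went both ways with FK228 relative to other genes. In heterozygous cultures 5 of 21 rose and 10 fell (median -0.14; camera, adjusted p = 0.388), and 3 rose without heterozygous solvent library 2 or heterozygous FK228 library 2. In wild type 4 rose and 9 fell (adjusted p = 0.331). With spike-in scaling 0 rose and 16 fell in heterozygous cultures, and 2 rose and 9 fell in wild type. None of 21 passed between genotypes in either treatment, 1 lower when adjusted over the list alone. Genes of the p53 response, which drive cell cycle arrest and apoptosis, were split too: 9 of 22 rose and 6 fell in heterozygous cultures (adjusted p = 0.406; 0 and 10 with spike-in scaling), and 7 rose (4 without wild-type FK228 library 7) and 5 fell in wild type, 8 and 5 when adjusted over the list alone (adjusted p = 0.389; 3 and 5 with spike-in scaling). Immediate early genes rose for 3 of 10 (1 with spike-in scaling) and fell for 1 in heterozygous cultures (adjusted p = 0.561), and rose for 2 and fell for 1 in wild type, 2 and 0 when adjusted over the list alone (adjusted p = 0.441). Cartilage genes fell for 4 of 6 and rose for 1 in each genotype (adjusted p = 0.406 in heterozygous, 0.389 in wild type). Endothelium and pericyte genes fell for 6 of 12 and rose for 1 in each genotype, 7 lower when adjusted over the list alone, with medians of -0.53 (adjusted p = 0.111; 11 lower with spike-in scaling) in heterozygous cultures and -0.52 in wild type (adjusted p = 0.0415; adjusted p = 0.496 with an estimated correlation). Of 8 red blood cell genes 1 was measured, and it did not pass in either genotype with FK228, nor between genotypes over all genes (log2 change 1.98 in solvent). The list's values for genotype in solvent (camera, adjusted p = 0.0152; adjusted p = 0.0804 with an estimated correlation) rest on that 1 gene and so test no set.

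Stria vascularis and melanocyte genes rose for 3 of 9 with FK228 in heterozygous cultures (1 without heterozygous solvent library 2, 4 or 5 or heterozygous FK228 library 4 or 5) and 1 when adjusted over the list alone, with a median of 0.24, or -0.55 and 0 raised with spike-in scaling (camera, adjusted p = 0.406). In wild type 3 fell (1 without wild-type solvent library 1, 2 or 4 or wild-type FK228 library 2 or 7), 1 when adjusted over the list alone, with a median of -0.49 (adjusted p = 0.286). Between genotypes in solvent, 1 of 18 deacetylase inhibitor genes (Tubb3; list adjusted p = 0.821) and 1 of 10 immediate early genes (list adjusted p = 0.548) were lower, and 1 of 18 interferon genes (H2-D1) was higher (list adjusted p = 0.548). Tubb3 lost its call without heterozygous solvent library 1 or 4, heterozygous FK228 library 3, wild-type solvent library 1 or 2, or any wild-type FK228 library (adjusted p up to 0.137). H2-D1 lost it without heterozygous solvent library 1 or 2 or wild-type solvent library 1, 3 or 4 (adjusted p up to 0.121). Between genotypes with FK228, interferon genes had a median of 0.27, or -0.45 with spike-in scaling, with 1 of 18 higher and 2 when adjusted over the list alone (adjusted p = 0.000108; adjusted p = 0.363 with an estimated correlation). Endothelium genes had 0.19, or -0.56 with spike-in scaling (adjusted p = 0.0251; adjusted p = 0.562 with an estimated correlation), and stereocilia genes -0.22 (adjusted p = 0.0251; adjusted p = 0.407 with an estimated correlation). In heterozygous cultures with FK228 against untreated wild type, all 14 macrophage markers were lower, with a median of -3.42 (adjusted p = 7.6e-11; adjusted p = 0.0589 with an estimated correlation).

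Genes that differed between genotypes in the same direction in both treatments numbered 105 higher and 55 lower in heterozygous cultures. Processed pseudogenes made up 25.7% of the higher ones (27 of 105) and 3.87% of all genes tested (Fisher's exact p = 2.18e-15), so reads shared with parent genes or pseudogene variants of the strain may account for these. Of the remaining genes 1 had no position in the annotation. Of the 132 others 52 had another within 1 Mb, where 10000 random draws gave a median of 24 and at most 51 (permutation p = 1e-04, the smallest they can give), so chromosome segments that differ between the mice of the genotypes may explain part of the list and stay open. The segment around Rest is argued against as the source, with 1 of the 159 genes with a position within 10 Mb of Rest, where random draws had a median of 0 and an upper bound of 3. An effect of the allele on the remaining genes stays open, untested.

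Lower REST targets in heterozygous cultures in solvent (median -0.79, 95% interval -1.43 to -0.43, 33 of 39 below 0) may reflect altered repression or fewer of the cells that express them. The intervals here come from resampling the genes of a list, which are not independent replicates. Hair cell genes outside the REST list had a median of -0.29 over 46 genes (-0.37 to -0.21), above that of the REST targets, so fewer hair cells are argued against as the whole explanation. Spiral ganglion neuron genes outside the REST list had -0.65 over 16 genes (-1.31 to -0.22), so fewer neurons could give the same picture and stay open. Genes outside the list were not checked for REST binding, so these values cannot separate fewer neurons from altered repression. Altered REST repression stays open too, and was not tested.

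Other splits of the same libraries into groups of the same sizes were tested. For genotype in solvent 1 of 35 splits, the real split, gave as many genes (253 in a fit of these libraries, at most 147 in the others). The split with 147 genes followed the share of reads outside genes. The real split also gave the most genes for FK228 in heterozygous cultures (1 of 35 splits, 7663 genes, at most 1 in the others) and in wild type (1 of 35, 8280, at most 0). It did so too for genotype with FK228 (1 of 35, 442, at most 0) and for heterozygous with FK228 against wild type in solvent (1 of 35, 8489, at most 0). The other splits mix the groups compared, so a real difference widens their spread and lowers their counts. A share of 1 in 35 is also the smallest these splits can give, so these shares alone do not exclude chance. For the interaction 2 of 100 splits gave 4 genes or more, the real split and a split with 46. The split with 46 divided the solvent libraries as the split with 147 did, and what it follows was not tested. Splits that mix the genotypes also carry a wider spread here, so that share does not exclude chance for these 4 genes. For genes lowered by genotype and raised by FK228 in heterozygous cultures, 4 of 70 splits gave 77 or more, at most 158 in the others. The split with 158 is the real split with its labels exchanged and carries the genotype difference itself. Without it 3 of 69 splits reached 77 (at most 155 in the others). With either assignment of the labels, 2 of 35 ways to divide the libraries did so. The splits with 84 and 155 genes divided the solvent libraries as the split with 147 did, which followed the share of reads outside genes. Whether chance can be excluded for the 77 genes depends on the way of counting and stays open.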
